A study of Homo sapiens with 12 samples.

How the data were processed

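Total RNA from human embryonic stem cells of the lines H9 and CT2 was measured on Illumina bead arrays. Each line was left untreated, given a mismatch shRNA or given an shRNA against JMJD1C, with 2 arrays per group, 6 groups and 12 arrays. Per the labels, RNA was extracted with the RNAqueous-4PCR kit and treated with DNase I, its quality was checked on an Agilent Bioanalyser, and it was labelled with biotin through the TotalPrep kit. The submitters' design text counts 6 lines with 2 replicates each, which equals the 6 groups of line and treatment. No label gives a slide, a date or a batch, and nothing says whether replicates were separate cultures.

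Per the file headers, the deposited non-normalized table holds the mean bead signal of each probe as an intensity. Per the file headers, the same table holds a detection p-value for each probe and array. The authors processed the arrays in GenomeStudio, whose version is not given in the sources used here. The 2 lines stand in separate blocks of that table, with 47320 probes for H9 and 47315 for CT2, and each block was joined by its own probe identifiers, which left 47314 probes in both. The authors also deposited a value table of 47323 probes in linear intensity, with 54 cells that hold no value. Its sorted columns were equal to within 1 percent for at least 99.99% of ranks within a line and for at most 26.33% across lines, so it was normalized separately in each line by a method that the labels do not name. Each of its 12 columns correlated best with the non-normalized column of its own sample, with a lowest r across probes of 0.9993 on the log2 scale. The authors' column medians were 179.9 and 179.9 for untreated H9, 179.9 and 179.8 for H9 with the mismatch shRNA, and 179.9 and 179.9 for H9 with the knockdown. They were 180.3 and 180.3 for untreated CT2, 180.3 and 180.2 for CT2 with the mismatch shRNA, and 180.3 and 180.3 for CT2 with the knockdown.

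The non-normalized intensities were used for every result. They were corrected for background by the normal-exponential model of limma 3.58.1 in R 4.3.3, with the negative controls inferred from the detection p-values and an offset of 16, then quantile-normalized over the 12 arrays and put on the log2 scale. Probes with a detection p under 0.05 on at least 2 arrays were kept, which left 25905. Of the 47314 probes, 30108 carried 1 gene symbol, 8 carried several and 17198 carried none. Among the kept probes these numbers were 19076, 4 and 6825. Where a gene had more than 1 kept probe, as 3911 genes did, the probe with the highest mean over all arrays stood for it, which gave 13951 genes. The files' Entrez identifiers found 13941 of these in the gene table of assembly GRCh38.p14, and 0 symbols were updated. That table was used for names and for which genes neighbour each other, not for positions. Of the 915 genes called in the main comparison, 275 had another kept probe, and for 31 of these a probe had the opposite sign. Probes with several symbols or with none stayed out of the counts of genes, 6829 in all, and were tested apart, a test added with the data in hand.

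A limma model with 1 mean per group was fitted to all 12 arrays, with an intensity trend and robust settings in the empirical Bayes step. Contrasts gave knockdown against mismatch shRNA as the mean of both lines and in each line, the difference of these responses between the lines, mismatch shRNA against no treatment, knockdown against no treatment, and H9 against CT2 without treatment. Tests were two-sided, and p-values were adjusted over all genes tested by the Benjamini-Hochberg method, with a threshold of 0.05 and no minimum fold. The group means share 1 estimate of the spread, since 2 arrays per group give too few degrees of freedom alone. The groups did not vary alike. The SD of the log2 difference between replicates was 0.6293 in CT2 mismatch and 0.4008 in CT2 knockdown. It was 0.3866 in H9 mismatch, 0.3706 in H9 knockdown, and 0.5125 and 0.3354 in untreated H9 and CT2. The shared spread can thus understate that of CT2 mismatch and overstate that of H9 mismatch and knockdown. Where every array of a group had a detection p of 0.05 or more, the fold is given as a bound against the lowest detected signal, and no fold is given where both groups lay there. Errors beside log2 fold changes are standard errors of the model, and errors beside group means are standard deviations of 2 arrays.

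Of 36 lists, 31 hold genes of pathways, lineages and complexes and 5 hold markers of cell types that a culture could contain. The 35 lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, with p-values adjusted over the lists. With an estimated correlation camera also has fewer degrees of freedom. Camera compares the members with all other genes. Fry tests whether the members move, on balance, one way, and compares them with no other genes. Members past the threshold were counted over all genes tested and also adjusted over the list alone.

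Samples, comparisons, tests, lists, alternatives and the rule for named genes were chosen before the data were examined. By that rule the main comparison names JMJD1C, the 10 largest rises and the 10 largest falls among genes past the threshold whose knockdown arrays lay on the same side of both mismatch arrays in each line, and in each list up to 4 members with the smallest p. Each other comparison names the 5 largest rises and the 5 largest falls past the threshold, with the same condition on single arrays within 1 line, and the difference between lines names its 10 largest values. Alternatives were no background correction with a floor of 16, an offset of 50, cyclic loess, median scaling, the authors' value table, a detection p under 0.01 on both arrays of a group, no filter, all kept probes, only the arrays of the groups compared, the replicate number as a block over all groups or within a line (statmod 1.5.0), array weights, an empirical Bayes step without trend and robust settings, a minimum of a log2 fold change of 1, and each of the 12 arrays left out in turn. With an array left out, the lone array of its group is assumed to vary like the other groups. The authors' table was not run for H9 against CT2, since each line was normalized alone. After the data had been seen, leaving out CT2 mismatch replicate 2 with H9 untreated replicate 1, and a block with crossed replicate numbers, were added.

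The test was run on simulated data of 13951 genes with the design of the 12 arrays, in which 50 genes were given each true log2 change. For the mean of both lines it called 6% of genes changed by 0.5, 42% of genes changed by 1 and 100% of genes changed by 2 or 4, with 4 false calls among 128. For 1 line it called 2%, 20%, 84% and 100% of these, with 3 false calls among 106. Left out were probes that stand in the block of 1 line only, probes that failed the filter and, from the counts of genes, the dimmer kept probes of genes with several. All per-sample columns were used. The number of arrays limits the precision of every value.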

Results

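RNA levels were measured in the human embryonic stem cell lines H9 and CT2, each untreated, with a mismatch shRNA as the control hairpin, or with an shRNA against JMJD1C, on 2 arrays per group. Across the 12 arrays the median non-normalized intensity ran from 150.2 to 196.8 and the mean from 1000 to 1692. Between 44.7% and 47.31% of probes were detected on an array, 21150 to 22384 probes. Replicates correlated across the tested genes with r between 0.9674 and 0.9909, a figure in which genes are not independent replicates. The lowest r belonged to CT2 with the mismatch shRNA, whose replicate 2 correlated better with H9 untreated replicate 1 (r = 0.9714) than with its own replicate. CT2 mismatch replicate 1 had its best match in CT2 knockdown replicate 1 (r = 0.9758), CT2 knockdown replicate 2 in CT2 untreated replicate 2 (r = 0.9871), and H9 untreated replicate 2 in H9 mismatch replicate 1 (r = 0.985). The first principal component held 31.13% of the variance and parted the lines, except that CT2 mismatch replicate 2 lay at -20.79, where the other CT2 arrays lay between 17.35 and 40.71 and the H9 arrays between -44.21 and -5.397. All p-values measure only the spread between these arrays.

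JMJD1C, a jumonji-domain protein of the family of H3K9 demethylases and the target of the knockdown, was lower on each knockdown array than on each mismatch and untreated array of its line. In H9 its log2 intensity was 12.49 and 11.54 on the untreated arrays, 11.95 and 11.51 on the mismatch arrays, and 10.60 and 10.71 on the knockdown arrays. In CT2 it was 11.48 and 11.94 on the untreated arrays, 12.06 and 12.38 on the mismatch arrays, and 10.77 and 10.71 on the knockdown arrays. Against mismatch shRNA, JMJD1C fell by 1.28 ± 0.19 on the log2 scale as the mean of both lines, to 41.2% of the mismatch level (adjusted p = 7.20e-04, lower on 4 of 4 knockdown arrays). Within H9 it fell by 1.08 ± 0.27 (47.2% of mismatch, adjusted p = 0.0438), and within CT2 it fell by 1.48 ± 0.27 (35.9% of mismatch, adjusted p = 0.00716). The responses of the lines differed by 0.40 ± 0.38, which did not pass (adjusted p = 0.784). The other kept JMJD1C probe gave -1.44 as the mean of both lines, and a further probe stayed at background on all arrays, with detection p from 0.1701 to 0.9312. Against untreated cells JMJD1C fell by 1.16 ± 0.19 (adjusted p = 0.00251), and mismatch shRNA against no treatment gave 0.12 ± 0.19 (adjusted p = 0.829), with -0.12 when H9 untreated replicate 2 was left out. The H9 call was lost without any 1 of its arrays, at adjusted p = 0.419 (-0.86) and 0.0996 (-1.30) without mismatch replicates 1 and 2 and at 0.291 (-1.03) and 0.207 (-1.14) without knockdown replicates 1 and 2. It was also lost without background correction (0.0528), with median scaling (0.122), with the authors' table (0.0503), with all kept probes (0.0696), with the replicate block (0.0722) and without trend and robust settings (0.120), in a range of 0.00110 to 0.122 over 14 alternatives. The CT2 call was lost without CT2 knockdown replicate 2 (-1.45, adjusted p = 0.110).

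**Figure D1:**
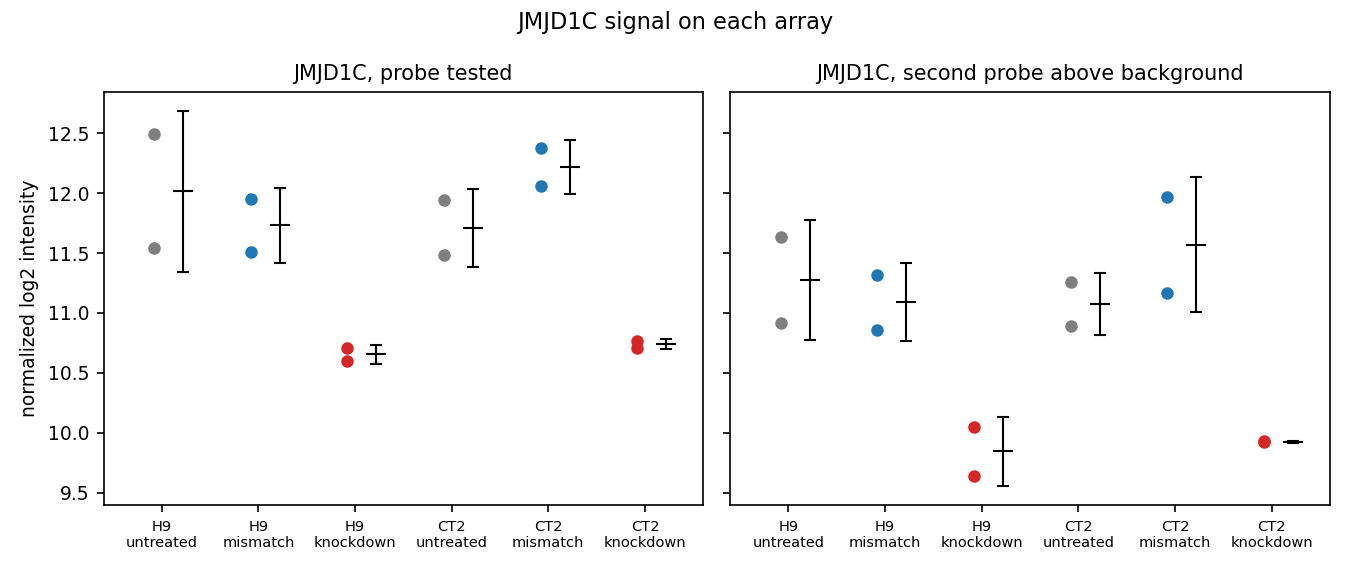
Normalized log2 intensity of JMJD1C on each of the 12 arrays, with 1 panel for each of the 2 probes above background. The untreated, mismatch and knockdown groups of both lines stand side by side in each panel. Points are arrays, and the mean ± SD of 2 arrays is drawn at the right of each group. For the probe tested, knockdown arrays lie between 10.60 and 10.77, and all other arrays lie between 11.48 and 12.49. For the second probe, knockdown arrays lie between 9.64 and 10.05, and all other arrays lie between 10.86 and 11.97.

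The main question was which transcripts differ when JMJD1C is knocked down, against the control hairpin and over both lines. LEFTY2, a secreted inhibitor of NODAL signalling, had the largest rise, 18.3-fold (log2 fold change 4.19 ± 0.17, adjusted p = 6.21e-10), with 4.36 in H9 and 4.03 in CT2. CER1, a secreted antagonist of NODAL, BMP and WNT ligands, rose by 2.08 ± 0.18 (adjusted p = 2.73e-06). NTS, the precursor of neurotensin, rose by 2.18 ± 0.14 (adjusted p = 8.76e-08), and the histone gene H2AC6 rose by 2.21 ± 0.18 (adjusted p = 1.04e-06). H2AC6 gave 3.10 in H9 and 1.32 in CT2, responses that differed between the lines. NPFFR2, a neuropeptide receptor, rose by 2.25 and KCNMB1, a subunit of a potassium channel, rose by 2.17 (adjusted p = 3.65e-06 and 5.71e-05). QNG1, an enzyme of queuosine salvage, rose at least 8.70-fold (adjusted p = 1.75e-08), BEX5 at least 8.24-fold (1.87e-07, at least 28.5-fold in H9 and a log2 fold change of 1.25 in CT2), and EBF2, a transcription factor, at least 2.68-fold (8.57e-05). CSRP1, a LIM-domain protein, also rose (adjusted p = 5.31e-07), but it lay at background in every H9 group and in CT2 mismatch arrays, so no fold is given for the mean. QNG1 lay at background in the mismatch arrays of both lines and in untreated H9 arrays, while in CT2 its untreated arrays (mean 9.72) lay above the knockdown arrays (9.17), so that there the mismatch arrays depart. BEX5 lay at background in the untreated and mismatch arrays of H9.

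SOX15 had the largest fitted fall. This SOX-family transcription factor fell by 2.36 ± 0.25 (adjusted p = 3.25e-05) and UTF1, a chromatin-associated factor of embryonic stem cells, fell by 1.96 ± 0.30 (adjusted p = 0.00101). DPPA5, an RNA-binding protein of early embryonic cells, fell to background in the knockdown of both lines and was at least 2.90-fold lower (adjusted p = 1.27e-04). EGR1, an immediate early transcription factor, fell by 2.06 ± 0.15 (adjusted p = 5.84e-07). TNNI3, the cardiac troponin I gene, fell by 2.26 ± 0.18 (1.03e-06), MMP24, a membrane-bound metalloproteinase, fell by 2.07 ± 0.22 (2.82e-05), and CADM1, a cell adhesion molecule, fell by 1.90 ± 0.21 (4.69e-05). TNNI3 gave -3.29 in H9 and -1.22 in CT2, responses that differed between the lines. SYT11, a synaptotagmin, fell by 2.16 ± 0.21 (1.25e-05), with -3.61 in CT2 and -0.70 in H9 (adjusted p = 0.333 there). WFIKKN1 fell by 2.08 ± 0.27 (1.91e-04), while against untreated cells it did not pass (adjusted p = 0.160). Its mean went from 8.34 untreated to 6.55 in the H9 knockdown, but in CT2 it lay at background without treatment and at 8.06 with the mismatch shRNA. BIK, a pro-apoptotic BH3-only protein, was at least 3.16-fold lower (0.00143). The naming rule required these 20 genes to lie in the stated direction on 4 of 4 knockdown arrays, so this adds no evidence. For CSRP1 every H9 group lay at background, where a direction has no meaning.

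Over all genes, 444 were higher and 471 lower in the knockdown, 915 of 13951 or 6.56%, and 123 and 165 of these changed at least 2-fold. Among the 101 genes past the threshold that the rule or the lists name, 90 had all 4 knockdown arrays beyond both mismatch arrays of their line, and 11 had 2 or 3. The rule required this of the largest rises and falls it named. Median scaling moved the median of all genes to 0.12 and the split to 610 higher and 313 lower, so that 66.1% of calls were rises in place of 48.5%. Without CT2 mismatch replicate 1 the counts were 1039 higher and 746 lower, and without CT2 knockdown replicate 2 they were 164 and 199. Leaving out an H9 array gave 181 and 224 without mismatch replicate 1, 239 and 247 without mismatch replicate 2, 233 and 273 without knockdown replicate 1, and 184 and 227 without knockdown replicate 2. Without CT2 mismatch replicate 2 and H9 untreated replicate 1 together, an alternative added after the data were seen, there were 731 higher and 909 lower.

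NODAL and activin signalling maintains pluripotency in human embryonic stem cells. Of 15 measured members of its list 7 rose, 1 fell and 7 did not pass, and adjusted over the list alone 8 rose and 5 fell. NODAL itself rose by 1.88 ± 0.16 (adjusted p = 1.97e-06) and PMEPA1, a SMAD-induced feedback inhibitor, rose by 1.40 ± 0.19 (3.34e-04), beside LEFTY2 and CER1. The list was higher than other genes with camera (adjusted p = 0.0320), with a median of 0.45, but not with an estimated correlation (adjusted p = 0.293 with an estimated correlation), and fry gave an adjusted p of 0.00235. The camera call was lost without CT2 mismatch replicate 1 (adjusted p = 0.301) and without CT2 knockdown replicate 1 (0.0698). In the list of the primitive streak and mesoderm 4 of 15 measured members rose, 0 fell and 11 did not pass, with 4 up adjusted over the list alone. These were NODAL, CER1, the growth factor gene FGF8 (1.98 ± 0.23, adjusted p = 7.68e-05) and the ligand gene WNT3 (1.06 ± 0.21, adjusted p = 0.00671). FGF8 also fell in mismatch against untreated cells, on 4 of 4 mismatch arrays, and did not pass for knockdown against no treatment. That list gave a median of 0.29, or 0.27 with bounds for members at background, and a camera adjusted p of 0.00127 (adjusted p = 0.293 with an estimated correlation and 0.205 with no filter). The NODAL and primitive streak lists share NODAL and CER1.

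**Figure D2:**
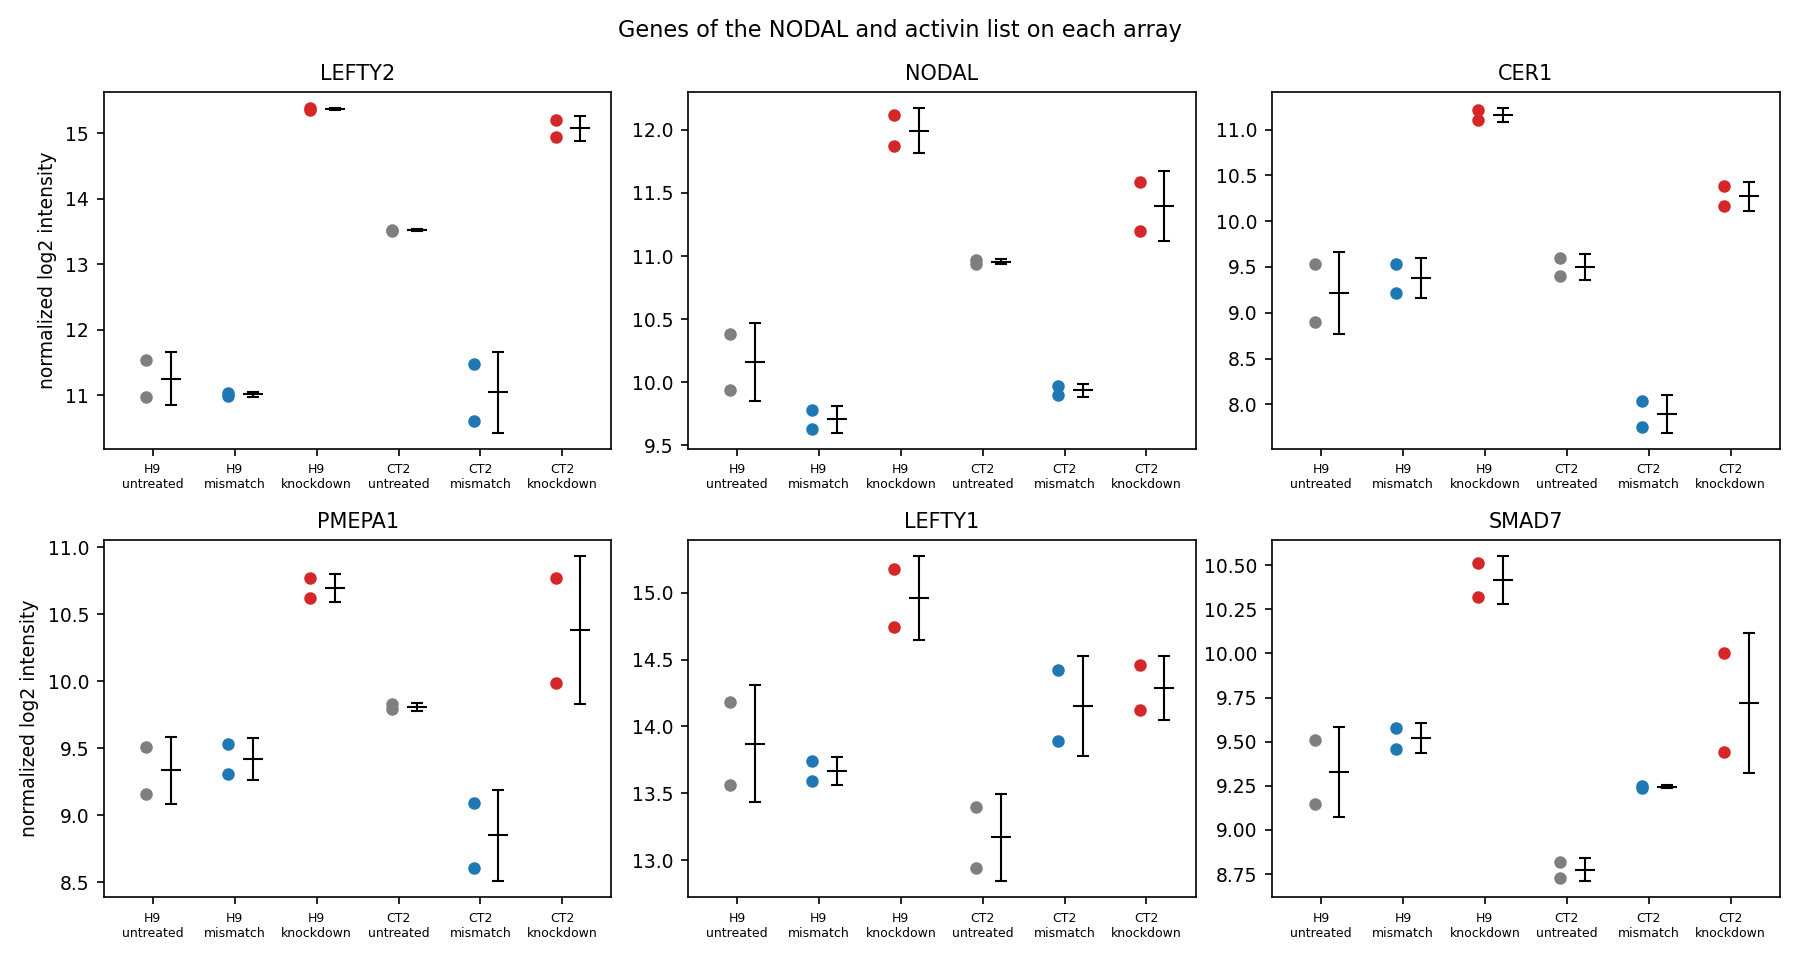
Normalized log2 intensity of LEFTY2, NODAL, CER1, PMEPA1, LEFTY1 and SMAD7, 1 panel per gene, for untreated (grey), mismatch (blue) and knockdown (red) arrays of both lines, with points for arrays and bars for the mean ± SD of 2 arrays. SMAD7 was chosen after its values were seen; LEFTY2 shows the widest gap between knockdown and mismatch arrays, a log2 fold change of 4.36 in H9 and 4.03 in CT2.

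Replication-dependent histone genes, which are transcribed in S phase, made up the list with the smallest p. Of 19 measured members 8 rose, 1 fell and 10 did not pass, and 13 rose and 1 fell adjusted over the list alone. Beside H2AC6, H2BC5 rose by 1.69 ± 0.19 (adjusted p = 3.92e-05), H4C8 rose at least 3.16-fold (1.02e-04) and H2BC12 rose by 1.23 ± 0.16 (2.16e-04). The median was 0.80, or 0.77 with bounds for members at background, with a camera adjusted p of 2.95e-09 (adjusted p = 0.293 with an estimated correlation, fry adjusted p = 0.00292). The same list was lower in mismatch than in untreated cells (camera adjusted p = 5.63e-05, 0.670 as adjusted p with an estimated correlation), as was the G1/S list (5.63e-05, 0.445 as adjusted p with an estimated correlation). Of 28 measured G1/S genes 5 rose, 1 fell and 22 did not pass, and 8 rose and 1 fell adjusted over the list alone; CCND2, a D-type cyclin, rose by 0.60 ± 0.12 (adjusted p = 0.00689). The G1/S list was higher with camera (adjusted p = 0.0330, 0.412 as adjusted p with an estimated correlation), with a mean of 0.02 in H9 and 0.35 in CT2. The histone list had means of 0.90 and 0.72 there. In knockdown against no treatment the G1/S list had a mean of -0.07 and the histone list one of 0.46. The histone rise thus cannot be read as a change in S phase. Of 30 measured G2/M genes 0 rose, 2 fell and 28 did not pass, and 3 fell adjusted over the list alone. TOP2A, a DNA topoisomerase of dividing cells, fell by 0.71 ± 0.14 (adjusted p = 0.00475), a call lost with median scaling (0.0565). TOP2A also rose in mismatch against untreated cells, on 4 of 4 mismatch arrays, and did not pass for knockdown against no treatment. The G2/M list was lower with camera (adjusted p = 0.0330, 0.412 as adjusted p with an estimated correlation), with a mean of -0.16 that became 0.007 under median scaling. The G1/S call was lost without CT2 mismatch replicate 1 (0.166), H9 mismatch replicate 2 (0.0707), H9 knockdown replicate 2 (0.0834) or CT2 knockdown replicate 2 (0.0979). The G2/M call was lost without CT2 mismatch replicate 2 (0.187), H9 mismatch replicate 1 (0.0557), H9 knockdown replicate 2 (0.0605) or CT2 knockdown replicate 1 (0.0609).

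The heat shock and interferon lists were lower with camera, through a part of their members. Of 13 measured heat shock genes 0 rose, 4 fell and 9 did not pass, with 4 falls adjusted over the list alone, and HSPA1A, an inducible HSP70 chaperone, fell by 1.33 ± 0.23 (adjusted p = 0.00240). The mean of the list was -0.30, beside 0.18 for mismatch against no treatment and -0.11 for knockdown against no treatment. The list was lower with camera (adjusted p = 0.0385, 0.293 as adjusted p with an estimated correlation), a call kept without CT2 knockdown replicate 1 and lost without each other array of the comparison: 0.0557 and 0.0609 without H9 mismatch replicates 1 and 2, 0.0554 and 0.0605 without H9 knockdown replicates 1 and 2, 0.0857 and 0.0573 without CT2 mismatch replicates 1 and 2, and 0.0798 without CT2 knockdown replicate 2. Of 32 measured interferon response genes 0 rose, 5 fell and 27 did not pass, and 1 rose and 7 fell adjusted over the list alone. HERC5, an ISG15 ligase, fell by 1.03 ± 0.14 (adjusted p = 2.77e-04) and IFI6 fell by 1.02 ± 0.19 (0.00353). Both passed in H9 and not in CT2, and the HERC5 response differed between the lines by -1.4 (H9 minus CT2). The interferon list was lower with camera (adjusted p = 0.0320, 0.486 as adjusted p with an estimated correlation), a call lost without H9 mismatch replicate 2 (0.0711), H9 knockdown replicate 2 (0.0834), CT2 mismatch replicate 1 (0.223) or CT2 knockdown replicate 1 (0.0841).

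The other lists did not pass with camera. Among pluripotency genes, the core list had 1 of 29 measured members up, 3 down and 25 not past the threshold, the same counts adjusted over the list alone (adjusted p = 0.221). UTF1 was the member with the smallest p. The naive list had 0 up, DPPA5 down and 10 of 11 members not past the threshold, with 1 up and 1 down adjusted over the list alone (adjusted p = 0.875); its mean was -0.02, or 0.01 at most under another scaling, where its median was 0.18 and camera pointed up. Germline genes had 1 of 15 up, 2 down and 12 not past the threshold, with 1 and 3 adjusted over the list alone (adjusted p = 0.346).

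Among lineage lists, neural progenitor genes had 0 of 29 measured members up, 5 down and 24 not past the threshold, and 2 up and 6 down adjusted over the list alone (camera adjusted p = 0.274, fry adjusted p = 0.0182). SFRP1, a secreted WNT modulator, fell by 0.63 ± 0.10 (adjusted p = 0.00138, 0.0521 with median scaling) and HES3, a transcriptional repressor, fell by 1.57 ± 0.30 (0.00472). HES3 gave -2.55 in CT2 and -0.59 in H9 (adjusted p = 0.672 there). Neuron genes had 3 of 26 up, 0 down and 23 not past the threshold, with 3 up adjusted over the list alone (adjusted p = 0.864), a median of -0.009 and a mean of 0.07. Those were STMN2 (1.71 ± 0.22, adjusted p = 2.20e-04), the neurofilament gene NEFM (0.92 ± 0.18, 0.00437) and MLLT11 (0.58 ± 0.12, 0.00665). All 3 passed in H9 and not in CT2, though no difference between the lines was called for them. Neural crest genes had 2 of 16 up, 0 down and 14 not past the threshold, with 3 up adjusted over the list alone (camera adjusted p = 0.346, fry adjusted p = 0.0167), and CDH6, a cadherin, rose by 1.52 ± 0.23 (6.32e-04). Endoderm genes had 2 of 13 up, 2 down and 9 not past the threshold, with 5 up and 4 down adjusted over the list alone (adjusted p = 0.875). CER1 and AFP, the alpha-fetoprotein gene (0.99 ± 0.19, adjusted p = 0.00409, higher on 3 of 4 arrays), rose, and the receptor gene KIT fell by 1.51 ± 0.16 (3.25e-05). AFP passed in CT2 and not in H9, and its responses differed by -1.95 (H9 minus CT2). In CT2 its mismatch arrays lay 1.37 from the untreated arrays and its knockdown arrays 0.59. Trophoblast and amnion genes had 0 of 14 past the threshold in either direction, also adjusted over the list alone (adjusted p = 0.274), and KRT7 had the smallest p (adjusted p = 0.0933). Surface ectoderm genes had 0 of 11 past the threshold either way, also adjusted over the list alone (adjusted p = 0.969), and PERP gave 0.52 ± 0.26 (adjusted p = 0.269).

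Among signalling lists, BMP and SMAD genes had 4 of 13 measured members up, 1 down and 8 not past the threshold, and 5 up and 3 down adjusted over the list alone (adjusted p = 0.689). ID3, a direct BMP target, fell by 1.22 ± 0.16 (adjusted p = 2.47e-04), while HEY1 rose by 1.5 ± 0.21 (4.65e-04) and TAGLN rose by 0.78 ± 0.13 (0.00185). WNT response genes had 0 of 15 up, 2 down and 13 not past the threshold, with 3 down adjusted over the list alone (camera adjusted p = 0.0689, fry adjusted p = 0.0167), and FRZB, a secreted WNT antagonist, fell by 0.97 ± 0.17 (0.00275). FGF and ERK genes had 0 of 19 up, EGR1 down and 18 not past the threshold, as they did adjusted over the list alone (adjusted p = 0.969); the mean was -0.05, or 0.08 under median scaling, the median was 0.14, and camera pointed up where fry pointed down. NOTCH genes had 2 of 13 up, 2 down and 9 not past the threshold, with 2 and 3 adjusted over the list alone (adjusted p = 0.969), and HEY1 was among those that rose; the mean of -0.007 became 0.09 under median scaling, and fry pointed up where camera pointed down. Published miR-302 family targets had 3 of 27 up, 1 down and 23 not past the threshold, the same counts adjusted over the list alone (adjusted p = 0.321), with LEFTY2 and CCND2 among the rises. LEFTY1 rose by 0.72 ± 0.17 (adjusted p = 0.0178, higher on 3 of 4 arrays), with 1.30 in H9 and 0.13 in CT2 (adjusted p = 0.809 there), a call lost without H9 mismatch replicate 2 (0.0680), H9 knockdown replicate 2 (0.0925) or CT2 knockdown replicate 1 (0.0708) and without trend and robust settings (0.0712, in a range of 0.00146 to 0.0712 over 13 alternatives).

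Among chromatin and RNA lists, H3K9 methylation genes had 1 of 27 measured members up, JMJD1C down and 25 not past the threshold, and 1 up and 2 down adjusted over the list alone (adjusted p = 0.969); the mean of -0.03 became 0.08 under median scaling, and the median was 0.08. UHRF1, which binds hemimethylated DNA, rose by 0.78 ± 0.15 (adjusted p = 0.00567). UHRF1 also fell in mismatch against untreated cells, on 4 of 4 mismatch arrays, and did not pass for knockdown against no treatment. It was also the riser among DNA methylation genes, with 1 of 10 up, 0 down and 9 not past the threshold, and 2 up and 1 down adjusted over the list alone (adjusted p = 0.648). Polycomb genes had 0 of 20 up, 1 down and 19 not past the threshold, with 1 and 1 adjusted over the list alone (adjusted p = 0.648), and the mean of -0.10 became 0.04 under median scaling. RNA interference genes had 1 of 13 up, 1 down and 11 not past the threshold, the same counts adjusted over the list alone (adjusted p = 0.875), and AGO1 rose by 0.92 ± 0.15 (0.00149); the mean of -0.04 became 0.10 under median scaling.

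Among stress and metabolism lists, p53 targets had 0 of 21 measured members up, 2 down and 19 not past the threshold, with 3 down adjusted over the list alone (camera adjusted p = 0.303, fry adjusted p = 0.0391), and a mean of -0.12 that became 0.01 under median scaling. DDB2, a DNA repair gene, fell by 0.84 ± 0.18 (adjusted p = 0.0119), a call lost without H9 mismatch replicate 2 (0.0737) or H9 knockdown replicate 2 (0.0754). Integrated stress and unfolded protein response genes had 3 of 31 up, 2 down and 26 not past the threshold, with 5 and 2 adjusted over the list alone (adjusted p = 0.372). DNAJC3, an endoplasmic reticulum co-chaperone, rose by 1.25 ± 0.24 (0.00419), and VLDLR, a lipoprotein receptor, fell by 1.08 ± 0.17 (0.00107). DNAJC3 also fell in mismatch against untreated cells, on 4 of 4 mismatch arrays, and did not pass for knockdown against no treatment. Glycolysis and hypoxia genes had 0 of 31 past the threshold, also adjusted over the list alone (adjusted p = 0.875), with ENO1 at 0.29 ± 0.08 (0.0526) and a list mean of 0.02 that became -0.003 under another scaling. Cholesterol and fatty acid synthesis genes had 1 of 24 up, 0 down and 23 not past the threshold, with 0 adjusted over the list alone (camera adjusted p = 0.364, fry adjusted p = 0.0410), and FASN gave 0.36 ± 0.15 (0.160). Ribosomal protein genes had 0 of 35 up, 1 down and 34 not past the threshold, with 0 adjusted over the list alone (adjusted p = 0.652), and RPL8 gave -0.23 ± 0.10 (0.187). Extracellular matrix and mesenchymal genes had 2 of 34 up, 3 down and 29 not past the threshold, with 6 and 5 adjusted over the list alone (adjusted p = 0.882). COL5A2 rose by 1.28 ± 0.19 (adjusted p = 5.02e-04) and COL1A1 fell by 1.05 ± 0.20 (0.00434), and the list mean of -0.007 became 0.12 under median scaling, with fry pointing up where camera pointed down.

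The lists of markers of other cell types did not pass. Fibroblast (feeder) markers had 2 of 11 measured members up, 1 down and 8 not past the threshold, the same counts adjusted over the list alone (adjusted p = 0.604); THY1, which stem cells also express, rose by 0.71 ± 0.12 (adjusted p = 0.00137) and COL1A1 fell. Haematopoietic markers had LCP1 up (1.67 ± 0.17, adjusted p = 2.08e-05), 0 down and 8 of 9 not past the threshold, as they did adjusted over the list alone (adjusted p = 0.875), with a median of -0.03 and a mean of 0.07. The LCP1 response differed between the lines by -1.85 (H9 minus CT2). In CT2 its mismatch arrays lay 2.04 from the untreated arrays and its knockdown arrays 0.554. Smooth and cardiac muscle markers had 1 of 7 up, 0 down and 6 not past the threshold, with 1 and 1 adjusted over the list alone (adjusted p = 0.875), a median of -0.03 and a mean of 0.04, where camera pointed down. That mean averages -0.23 in H9 and 0.32 in CT2. Astrocyte and oligodendrocyte markers had 0 of 5 past the threshold, also adjusted over the list alone (adjusted p = 0.969), and SOX10 gave -0.34 ± 0.28 (0.550). Of the endothelial markers 4 were measured, too few for a test: TEK, the angiopoietin receptor, fell by 1.62 (adjusted p = 3.28e-05), and KDR gave 0.27 (0.684) and EGFL7 -0.61 (0.144), while CLDN5 (0.704) lay at background in groups and has no fold.

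**Figure D3:**
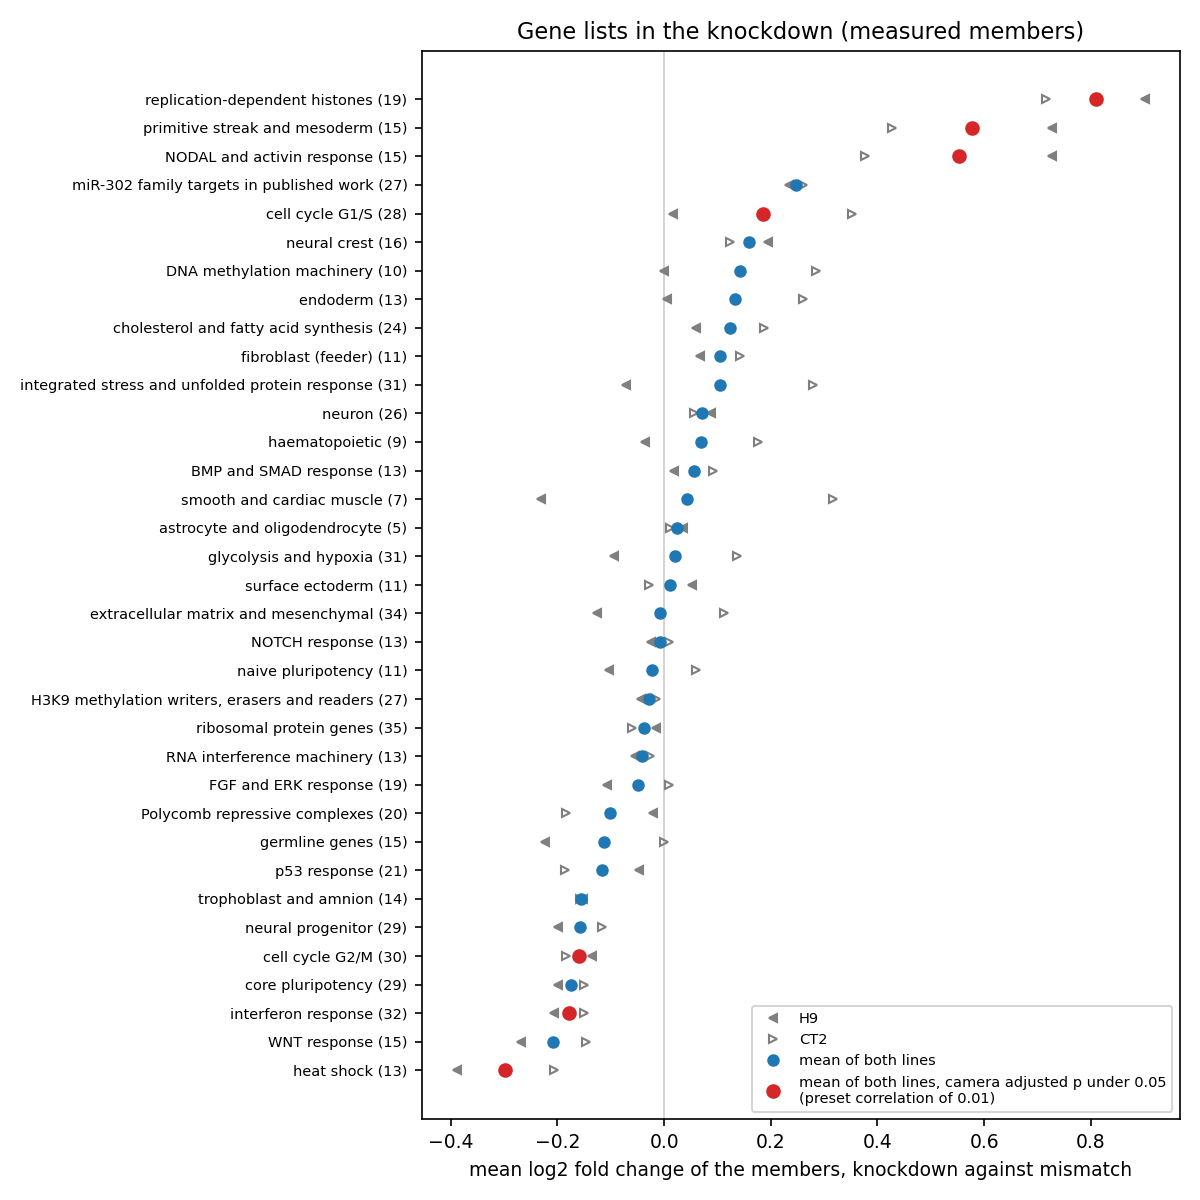
Mean log2 fold change of the members of each of the 35 tested lists, knockdown against mismatch shRNA, as points for the mean of both lines and triangles for H9 and CT2, with red for lists with a camera adjusted p under 0.05. Replication-dependent histones (0.81), primitive streak and mesoderm (0.58) and NODAL and activin response (0.55) lie farthest right. The red list G2/M changes sign under median scaling, which moves the median of all genes to 0.12. All 7 red calls are lost with an estimated correlation, where the test also has fewer degrees of freedom.

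In H9 alone, LEFTY2 rose 20.5-fold (4.36 ± 0.24, adjusted p = 2.41e-08). CRYZ, a quinone reductase, rose at least 57.6-fold (1.72e-11) and its neighbour TYW3, an enzyme of tRNA modification, at least 15.0-fold (4.58e-09), both at background in the H9 mismatch arrays. Their means were 10.28 and 8.86 on untreated H9 arrays, beside 11.87 and 9.93 on knockdown arrays. BEX5 rose at least 28.5-fold (2.66e-08) and QNG1 at least 8.45-fold (9.49e-07), from background in untreated and mismatch arrays. CAT, the catalase gene, fell to background and was at least 11.3-fold lower (4.90e-07), and its other kept probe gave -2.18. TEK fell by 3.40 ± 0.25 (4.89e-07), TNNI3 fell by 3.29 ± 0.25 (8.42e-07), SOX15 fell by 3.05 ± 0.35 (1.06e-04), and SCG2, a secretory granule protein, was at least 4.94-fold lower (8.71e-04). The naming rule required each of these genes to lie beyond both mismatch arrays on 2 of 2 knockdown arrays.

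Lists past the threshold in H9 were histones, primitive streak, NODAL and heat shock. Histone genes had 7 of 19 members up, 1 down and 11 not past the threshold, with 10 and 1 adjusted over the list alone (camera adjusted p = 1.30e-09, 0.184 as adjusted p with an estimated correlation), and H2AC6 rose by 3.10 (1.08e-06). Primitive streak genes had 3 of 15 up, 0 down and 12 not past the threshold, with 5 up adjusted over the list alone (2.75e-05, 0.221 as adjusted p with an estimated correlation, 0.178 with no filter), and FGF8 rose by 2.98 (6.29e-05). The H9 mismatch arrays also lay below both untreated H9 arrays for FGF8, which did not pass for knockdown against no treatment over both lines. NODAL genes had 5 of 15 up, 0 down and 10 not past the threshold, with 7 up and 2 down adjusted over the list alone (1.71e-04, 0.184 as adjusted p with an estimated correlation), and NODAL rose by 2.29 (1.33e-05). Heat shock genes had 0 of 13 up, 3 down and 10 not past the threshold, with 4 down adjusted over the list alone (0.0313, 0.227 as adjusted p with an estimated correlation), and HSPA1B fell by 1.46 (8.71e-04). Its H9 mismatch arrays lay 1.36 from the untreated arrays and its knockdown arrays 0.098. The heat shock call was also lost without H9 mismatch replicate 1 (0.0535) or H9 knockdown replicate 1 (0.0520). In total 138 genes were higher and 218 lower, 123 and 180 of them at least 2-fold. Fitting only the groups compared gave 293 and 452, and array weights gave 323 and 498. The counts were 51 and 68 without mismatch replicate 1, 49 and 68 without mismatch replicate 2, 53 and 63 without knockdown replicate 1, and 47 and 71 without knockdown replicate 2, and median scaling gave 157 and 152, or 50.8% rises in place of 38.8%.

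In CT2 alone, LEFTY2 rose 16.4-fold (4.03 ± 0.24, adjusted p = 1.18e-07), of which 1.56 lies between knockdown and untreated arrays and the rest in a lower level of the mismatch arrays (-2.47). CSRP1 rose at least 44.0-fold (6.26e-08), MTLN, a mitochondrial microprotein, at least 14.6-fold (1.75e-07), QNG1 at least 8.95-fold (2.65e-06) and TRIM68, a RING-domain protein, at least 5.52-fold (1.01e-06), all from background in the CT2 mismatch arrays. In this order their means were 9.05, 9.57, 9.72 and 8.46 on untreated CT2 arrays, beside 11.47, 9.88, 9.17 and 8.48 on knockdown arrays. SYT11 fell by 3.61 ± 0.30 (2.73e-06), CXCL5, a chemokine, was at least 7.45-fold lower (2.69e-06), and the pseudogene NAP1L6P fell by 2.42 ± 0.31 (4.54e-04). HES3 fell by 2.55 ± 0.42 (0.00476) and WFIKKN1 fell by 2.47 ± 0.38 (0.00230), calls lost without CT2 knockdown replicate 2 (-2.24 and -2.10). The naming rule required each gene named here to lie beyond both mismatch arrays on 2 of 2 knockdown arrays.

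Lists past the threshold in CT2 were histones and G1/S. Histone genes had 4 of 19 members up, 0 down and 15 not past the threshold, with 10 up adjusted over the list alone (camera adjusted p = 1.36e-05, 0.539 as adjusted p with an estimated correlation), and H4C8 rose by 1.76 (0.00663). G1/S genes had 3 of 28 up, 0 down and 25 not past the threshold, with 10 up and 1 down adjusted over the list alone (0.00247, 0.539 as adjusted p with an estimated correlation), and CCNE1, cyclin E, rose by 0.73 (0.0432). The G1/S call was also lost without CT2 mismatch replicate 1 (0.117). In total 384 genes were higher and 252 lower, and median scaling gave 424 and 147, or 74.3% rises in place of 60.4%. The spread is shared with the H9 groups, so these counts cannot be ranked against those of H9. The counts were 1199 and 631 without mismatch replicate 1, 184 and 165 without mismatch replicate 2, 135 and 111 without knockdown replicate 1, and 30 and 10 without knockdown replicate 2. They also moved to 225 and 136 with the replicate block, 251 and 154 with the block within a line, 623 and 439 with crossed replicate numbers, 36 and 14 with only the CT2 groups fitted, 126 and 60 with array weights, 201 and 137 without trend and robust settings, and 237 higher with a minimum of 2-fold.

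The responses of the lines shared LEFTY2, CER1, NODAL and UTF1 among other genes. Of the 356 genes called in H9, 293 had the same sign in CT2, and of the 636 called in CT2, 495 had the same sign in H9. Genes called in both with the same sign numbered 89, with 41 higher and 48 lower where independent lists would give 3.798 and 3.938, and 4 were called with opposite signs. The values for independent lists are too low a reference, since both lines are tested with the same spread for each gene. The log2 fold changes of the lines correlated across genes with r = 0.314 and rho = 0.268, in which genes are not independent replicates. The response differed for 58 genes. For genes at background in a group the difference, H9 minus CT2 on the log2 scale, is a bound. It was at least 5.77 for CRYZ (adjusted p = 5.42e-09), 4.07 for TYW3 (6.19e-07) and 3.59 for BEX5 (9.77e-05). For CXCL5 it was at least 4.87 (1.10e-06), since CXCL5 rose by 1.97 in H9 (7.42e-04) and was at least 7.45-fold lower in CT2. MTLN (-3.55 or beyond, 4.15e-05) and TRIM68 (-2.77 or beyond, 3.43e-05) had the larger difference between knockdown and mismatch arrays in CT2. There the mismatch arrays depart: they lay 3.96 and 3.41 from the untreated arrays, and the knockdown arrays lay 0.315 and 0.021 from them. CAT (-3.48 or beyond, 6.10e-05) and TEK (-3.57 ± 0.35, 3.43e-05) fell in H9, and TEK gave 0.16 in CT2. CSRP1 (1.17e-05) and TRIM4 (2.04e-04) also differed, with no size given since both groups of a line lay at background, and the other kept probe of TRIM4 had the opposite sign. The count was 528 without CT2 mismatch replicate 1, 23 without H9 mismatch replicate 1 or 2, 25 and 36 without H9 knockdown replicates 1 and 2, and 21 and 26 without CT2 knockdown replicates 1 and 2, and it was 37 without trend and robust settings. Of the 58, 17 had the higher value in H9 and 41 the lower, and median scaling gave 33 and 39, or 45.8% in place of 29.3%.

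**Figure D4:**
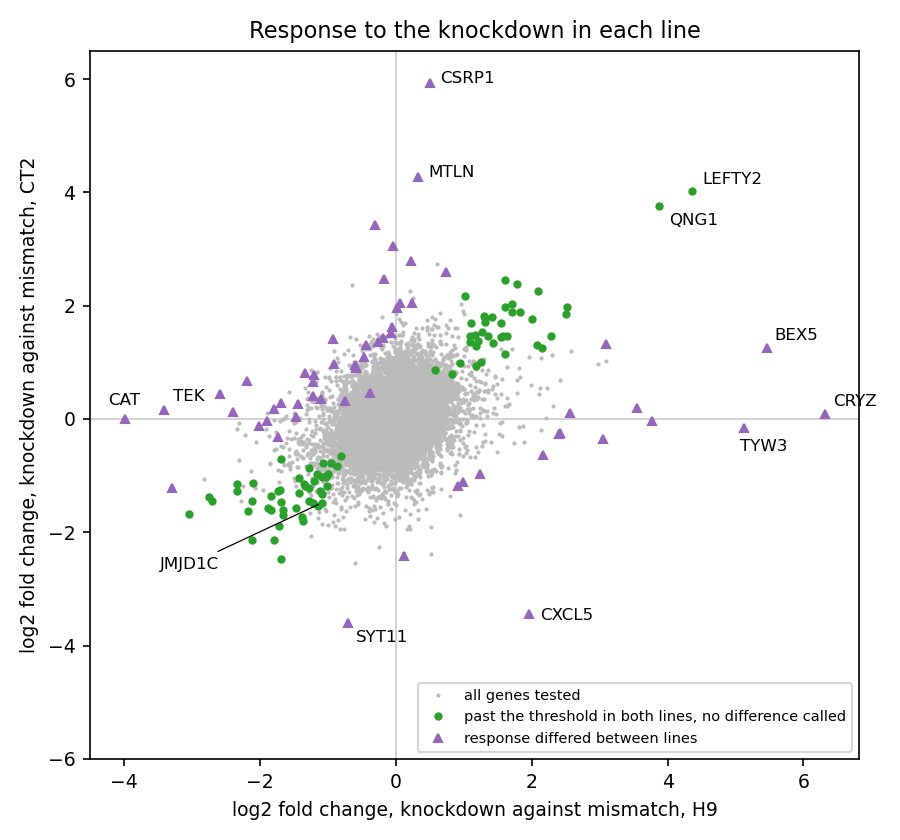
Log2 fold change of each gene in H9 (x axis) and CT2 (y axis), knockdown against mismatch shRNA, with green points for genes called in both lines without a difference between them and purple triangles for the 58 genes whose response differed. LEFTY2 lies at 4.36 and 4.03, and CRYZ and CSRP1 lie far from the diagonal, with fitted values that depend on the offset.

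Mismatch shRNA against no treatment shows what the control hairpin and its delivery went with. The largest falls were genes at background in mismatch arrays of a line: TRIM61 was at least 4.66-fold lower (adjusted p = 4.81e-05), CRYZ at least 3.98-fold (1.04e-06) and MTLN at least 3.52-fold (4.81e-05), while QNG1 (7.78e-05) and CSRP1 (6.02e-04) fell with no fold given, both at background in H9 with and without the mismatch shRNA. TRIM61 was lower in both lines. The value of CRYZ comes from H9, where its mean went from 10.28 to 5.56, against 12.06 to 12.33 in CT2. That of MTLN comes from CT2, with 9.57 to 5.6, against 9.65 to 9.57 in H9. LEFTY2 fell by 1.36 (adjusted p = 9.98e-04), with -2.47 in CT2 and -0.24 in H9 (lower on 2 of 4 arrays), NODAL fell by 0.74 (0.0332) and FGF8 fell by 1.59 (0.00341). PLPP7 rose by 1.63 ± 0.26 and HPN, a serine protease, rose by 1.45 ± 0.23 (both adjusted p = 0.00702). HRC, a calcium-binding protein of muscle, rose at least 2.43-fold (0.0168), SGSM1 rose by 1.41 ± 0.25 (0.0145) and HGC6.3 rose at least 2.35-fold (0.0268). Without CT2 untreated replicate 2 all 5 rises were lost, at 0.0610 for PLPP7, 0.0555 for HPN, 0.0821 for HRC and SGSM1 and 0.0992 for HGC6.3. Without H9 mismatch replicate 1 the rises of HPN (0.0614), HRC (0.0695), SGSM1 (0.101) and HGC6.3 (0.0930) were lost. HRC was also lost without H9 mismatch replicate 2 (0.0762), HRC and SGSM1 without H9 untreated replicate 1 (both 0.0594) or CT2 untreated replicate 1 (0.0918 and 0.0731), and HGC6.3 in 6 of the 8 omissions, up to 0.141, and in 3 of 13 other alternatives, up to 0.0610.

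Camera placed the G1/S and histone lists lower with the mismatch shRNA, while the G2/M list had a mean of 0.14 and did not pass (adjusted p = 0.0737). Of 28 G1/S genes 0 rose, 0 fell and 28 did not pass, while 8 fell adjusted over the list alone, and the list was lower with camera (adjusted p = 5.63e-05, 0.445 as adjusted p with an estimated correlation). Of 19 histone genes 0 rose, 1 fell and 18 did not pass, with 1 fall adjusted over the list alone (5.63e-05, 0.670 as adjusted p with an estimated correlation), and H4C8 was at least 1.74-fold lower (0.0408). In total 80 genes were higher and 86 lower, 36 and 35 at least 2-fold, and 17 of the 23 named or listed genes past the threshold had 4 of 4 mismatch arrays beyond both untreated arrays of their line. The counts were 345 and 238 without CT2 mismatch replicate 2, the array that stands apart, and 152 and 259 without CT2 mismatch replicate 1. They were 23 and 37 without H9 untreated replicate 1, 3 and 19 and 11 and 22 without H9 mismatch replicates 1 and 2, and 4 and 18 and 1 and 16 without CT2 untreated replicates 1 and 2. Other settings that moved them were only the groups compared (22 and 39), no filter (53 higher), all kept probes (47 higher), array weights (38 higher), the replicate block (35 and 48), the block within a line (37 and 45), the empirical Bayes step without trend and robust settings (51 and 52) and the minimum of 2-fold. This comparison shares the mismatch arrays with the main one, where they enter with the opposite sign. Of genes called in both, 79 went opposite ways, 0 were higher in both and 2 lower in both. The r across genes was -0.537, beside -0.4995 in simulated unchanged groups. With the mismatch arrays split, the 4 ways gave 32.75 opposite, 1.75 higher and 5.25 lower in both on average, and r was -0.218. A gene that moves on the mismatch arrays alone can thus be called in both comparisons.

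Knockdown against no treatment asks the question with the other control. LEFTY2 rose by 2.84 ± 0.17 (adjusted p = 2.53e-07), BEX5 at least 7.28-fold (9.49e-07), ADAMTSL2 at least 4.84-fold (7.54e-05), HGC6.3 at least 3.98-fold (4.05e-04), and RAC2, a small GTPase, by 1.998 ± 0.25 (2.67e-04). SYT11 fell by 2.67 ± 0.21 (3.37e-06), SOX15 fell by 2.47 ± 0.25 (2.96e-05), CADM1 fell by 2.13 ± 0.21 (2.89e-05), TEK fell by 2.11 ± 0.17 (4.38e-06), and TRIM61 was at least 4.66-fold lower (1.84e-05). Of the 57 named or listed genes past the threshold, 48 had 4 of 4 knockdown arrays beyond both untreated arrays of their line.

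The NODAL, primitive streak and histone lists passed here as they did against the mismatch shRNA, in both cases only with the preset correlation (adjusted p = 0.341, 0.513 and 0.341 with an estimated correlation). The other lists that had passed there did not pass here. G1/S had the opposite sign, with a mean of -0.07 (adjusted p = 0.362). G2/M had a mean of -0.01 that became 0.06 under median scaling (0.804). Interferon had a mean of -0.08 (0.184) and heat shock one of -0.11 (0.362). Core pluripotency, miR-302 targets, WNT and p53 passed here, also only with the preset correlation (adjusted p = 0.341, 0.513, 0.341 and 0.341 with an estimated correlation), and had not passed against the mismatch shRNA. NODAL genes had 6 of 15 members up, 0 down and 9 not past the threshold, with 6 and 1 adjusted over the list alone (camera adjusted p = 0.0174, 0.341 as adjusted p with an estimated correlation, lost without H9 untreated replicate 2 at 0.0831), and NODAL rose by 1.14 (5.47e-04). Primitive streak genes had 3 of 15 up, 0 down and 12 not past the threshold (0.0216, 0.513 as adjusted p with an estimated correlation), a call lost with no filter (0.366) and without H9 untreated replicate 2 (0.0687), H9 knockdown replicate 1 (0.0572) or CT2 untreated replicate 1 (0.0805). Histone genes had 6 of 19 up, 1 down and 12 not past the threshold, with 8 and 1 adjusted over the list alone (2.96e-04, 0.341 as adjusted p with an estimated correlation), and H2AC6 rose by 1.72 (2.96e-05). Published miR-302 targets had 4 of 27 up, 1 down and 22 not past the threshold, with 8 and 1 adjusted over the list alone (0.00916, 0.513 as adjusted p with an estimated correlation). LEFTY2, TXNIP (1.45, 0.00194), LEFTY1 (1.11, 0.00150) and CCND2 (0.73, 0.00252) rose. TXNIP also rose in mismatch against untreated cells, on 4 of 4 mismatch arrays, and did not pass for knockdown against mismatch shRNA. Core pluripotency genes had 0 of 29 up, 2 down and 27 not past the threshold (0.0174, 0.341 as adjusted p with an estimated correlation, lost without H9 untreated replicate 1 at 0.0685 or H9 knockdown replicate 1 at 0.0572), with UTF1 (-1.77, 0.00333, lower on 3 of 4 arrays) and ZFP42 (-0.58, 0.0134, lower on 2 of 4) past the threshold. The ZFP42 value comes from H9, and against the mismatch shRNA ZFP42 gave -1.22 in H9 and 0.66 in CT2 (6.62e-04 and 0.0390). WNT genes had 0 of 15 up, 3 down and 12 not past the threshold, with 1 up and 4 down adjusted over the list alone (0.0408, 0.341 as adjusted p with an estimated correlation), and FRZB fell by 0.91 (0.00732). That call was lost without H9 untreated replicates 1 (0.0565) or 2 (0.114), H9 knockdown replicate 1 (0.165), CT2 untreated replicate 2 (0.134) or CT2 knockdown replicate 2 (0.103), and with no filter (0.148). Genes of the p53 response had 0 of 21 past the threshold and a lower list (0.0174, 0.341 as adjusted p with an estimated correlation, lost without H9 untreated replicate 2 at 0.0710).

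In total 218 genes were higher and 260 lower than in untreated cells. The comparisons share the knockdown arrays, so they overlap by construction: 120 genes were higher and 148 lower in both and 0 went opposite ways. Independent lists of these sizes would give 6.94 and 8.78, a value that leaves out the shared arrays. In 50 simulated sets of unchanged groups the overlap was 0.04 and 0.06 on average, since such groups have almost no calls, so neither value measures a shared effect. With the knockdown arrays split so that each comparison used its own, the 4 ways gave 21.5 higher and 33 lower in both on average, where independent lists would give 0.274 and 0.504, and r across genes was 0.439 in place of 0.630. Simulated unchanged groups that share arrays gave 0.5001, with a covariance of 0.0227 beside the observed 0.0844. The counts against untreated cells were 137 and 170 without H9 untreated replicate 1, 62 and 88 and 88 and 93 without CT2 untreated replicates 1 and 2, 82 and 101 and 105 and 152 without H9 knockdown replicates 1 and 2, and 94 and 141 and 108 and 135 without CT2 knockdown replicates 1 and 2. Fitting only the groups compared gave 382 and 401, array weights gave 427 and 448, and a minimum of 2-fold gave 81 and 97. Median scaling gave 253 and 162, or 61% rises in place of 45.6%.

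Without treatment, H9 and CT2 differed most in MEG3, an imprinted long noncoding RNA, which was lower in H9 by a log2 value of -8.74 ± 0.30 (adjusted p = 2.72e-11), with -7.06 for its other kept probe. ZNF667-AS1 was at least 30.4-fold lower in H9 (3.18e-10), MLKL, the effector of necroptosis, at least 19.7-fold (1.25e-08) and DNAJA4, a co-chaperone, at least 14.5-fold (3.19e-08), and SYT11 gave -4.84 ± 0.30 (3.19e-08). FAM217B was at least 42.3-fold higher in H9 (3.18e-10), RPL22L1, a ribosomal protein paralogue, at least 8.79-fold (1.93e-06), ZNF558 at least 8.56-fold (3.20e-06) and ZNF280B at least 6.98-fold (3.20e-06), and LOC644936 gave 3.88 ± 0.57 (0.00151). All 138 named or listed genes past the threshold had both H9 arrays beyond both CT2 arrays. The rule required this of the largest differences it named. Of 15 NODAL list members 1 was higher in H9, 3 were lower and 11 did not pass. LEFTY2 gave -2.26 (adjusted p = 2.96e-05), NODAL -0.80 (0.0239) and LEFTY1 0.70 (0.0587). The mean of that list, -0.14, became 0.03 under median scaling, and the list did not pass (camera adjusted p = 0.742).

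The neural progenitor list was higher in H9 with camera, with 7 of 29 members higher, 2 lower and 20 not past the threshold, and 11 and 2 adjusted over the list alone (camera adjusted p = 0.0182, 0.349 as adjusted p with an estimated correlation, 0.0770 with no filter and 0.0552 without H9 untreated replicate 1). SFRP1 gave 1.29 (adjusted p = 3.94e-05) and the zinc finger gene ZIC2 gave 1.37 (1.48e-04). The histone list was lower in H9, with 0 of 19 higher, 5 lower and 14 not past the threshold, and 7 lower adjusted over the list alone (9.47e-04, 0.827 as adjusted p with an estimated correlation), and H4C8 gave -2.34 (2.98e-04). In total 835 genes were higher and 1222 lower in H9, 14.7% of those tested, 494 and 740 at least 2-fold. The counts were 425 and 479 without H9 untreated replicate 1, 147 and 233 without CT2 untreated replicate 1, and 198 and 401 without CT2 untreated replicate 2, and median scaling, which moved the median of all genes to 0.12, gave 1105 and 617, or 64.2% higher in place of 40.6%.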

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

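The tests of explanations in this part were chosen after the results they bear on were seen, and the test of probes without exactly 1 gene symbol was added with the data in hand, while the test of the difference between lines and the counts over other splits of the arrays were planned.

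The response to the knockdown differed between H9 and CT2 for 58 genes by a test of the difference itself, which is why they stand here. Of the 10 with the largest absolute difference, all but TEK (-3.57 as H9 minus CT2 on the log2 scale) were at background in at least 1 group, so that their fitted values depend on the offset and only the bounds are sizes. The fitted value was 6.23 for CRYZ (bound 5.77), 5.41 for CXCL5 (4.87), 5.29 for TYW3 (4.07), 4.21 for BEX5 (3.59), -3.98 for CAT (-3.48), -3.96 for MTLN (-3.55) and -3.73 for TRIM68 (-2.77). For TRIM4 (fitted 3.81) and CSRP1 (fitted -5.43) both groups of a line lay at background, so no size is given.

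Of the 58 genes, CRYZ and TYW3 neighbour each other on GRCh38.p14, as do NLRP7 and NLRP2, and 0.85% of 10000 random gene sets held as many neighbouring pairs. That test was run under 3 definitions: among 8 genes at background in 1 group and at least 4-fold higher in the others of the line there was 1 pair (CRYZ with TYW3, 0.07% of random sets), and among 4 such genes at 8-fold there were 0 pairs (100% of random sets), so loss or silencing of a chromosome segment cannot be told apart from chance, since the answer turns on the definition and the pairs cover 4 of the 58 genes. A change in the mismatch in place of the knockdown cultures predicts mismatch arrays farther from the untreated arrays. This held for 44.8% of the 58 (26 genes, exact 95% interval 31.7 to 58.5), so the interval over both lines leaves it open. The lines lean opposite ways: it held for 7 of the 31 genes with the larger response in H9 and 19 of the 27 in CT2. The sets of 8 and of 4 genes are earlier definitions of the pattern and hold QNG1, which is not among the 58. They were at background in mismatch or untreated groups for 75% (34.9 to 96.8) and 100% (39.8 to 100). Those shares decide nothing, since 4 of the 6 groups are mismatch or untreated and no gene was off in an untreated group alone. Without CT2 mismatch replicate 2, 70.7% of the 58 (41 genes) still passed, which lies between the bounds set for that array as the cause and against it. Differences between the lines as biology, including drift of separate cultures, also stay open and were not tested.

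Of the NODAL list, 7 genes rose in the knockdown, a pattern a fall in the mismatch arrays alone could also give. Against untreated arrays the median of the 7 risers was 1.11, with 1.36 in H9 (bootstrap interval 1.08 to 1.94) and 0.77 in CT2 (0.44 to 1.12). The 7 were chosen by their rise on these same knockdown arrays, which can raise these medians. The bootstrap resamples genes, so its intervals do not measure the spread of arrays. In H9 the mismatch arrays lay at a median of -0.03 from the untreated arrays, which argues against such a fall as the whole cause there. In CT2 the medians do not decide it. There, 5 of these genes also lay lower in mismatch than in untreated arrays (LEFTY2 -2.47, median of all 7 -0.96), and LEFTY1 (0.99) and SMAD7 (0.47) lay higher. For those 5 the larger share of the CT2 difference lies in the mismatch arrays (against untreated arrays the CT2 knockdown gave 1.56 for LEFTY2, 0.77 for CER1, 0.57 for PMEPA1, 0.44 for NODAL and 0.13 for BAMBI). Cross-hybridisation between the LEFTY1 and LEFTY2 probes is argued against as the whole cause by 5 other risers of the list, though it leaves the values of LEFTY1 and LEFTY2 themselves uncertain. Cells leaving pluripotency for mesoderm or endoderm cannot be told apart from a change within stem cells, since the 25 primitive streak and endoderm genes outside the list had a median of 0.17 (bootstrap interval 0.012 to 0.447), with 3 up and 2 down. An effect of the lower JMJD1C level stays open as a hypothesis, as does an effect of this hairpin on other targets, which only a further hairpin could test.

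CT2 mismatch replicate 2 stood apart from replicate 1. A label swap with an H9 array is argued against by 30 genes over 8-fold apart between the untreated lines, on which it lay at 0.076 of the way from CT2 to H9. A trend with intensity as the whole cause is argued against by r = 0.9661 with its replicate across kept probes after cyclic loess, below the lowest other pair (0.9763). Cyclic loess does not remove noise from weaker signal, so a dimmer array stays open. The mean non-normalized intensity of CT2 mismatch replicate 2 was the lowest of all arrays (1000, beside 1468 for its replicate). Its median (160.7) and its share of detected probes (45.41%) lay within the range of the other arrays. In the main normalization r across kept probes was 0.9637. RNA of H9 cells may still be mixed in to some extent: of 4 genes at background on the other CT2 arrays and high in all H9 groups, 0 were detected on it (0%, exact upper bound 60.2%), too few to decide, and a stricter choice of 2 genes also gave 0. The array's culture is an open explanation that nothing in the files tests.

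Chance as the source of the counts was tested by splitting the 8 arrays of a comparison into 4 and 4 in a model with the line as a term, in 34 ways, the split into the lines having no fit. For knockdown against mismatch the real split gave 474 genes and the highest other split 1, so that 1 of the 34 gave as many. For knockdown against no treatment the real split gave 354 genes and the highest other 2, again 1 of the 34. In both, the labels gave more genes than any other split. This does not exclude chance, since 34 ways allow no smaller share. The other splits also mix the real groups, which widens the spread within each side and lowers their counts. A difference between single cultures could give the same result, since nothing says whether replicates were separate cultures. For mismatch against no treatment the real split gave 2 genes, 2 of the 34 gave as many, and chance cannot be excluded. The highest other, 82 genes, set both H9 untreated arrays, H9 mismatch replicate 1 and CT2 mismatch replicate 2 against the rest, which points to a structure of the samples.

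Probes without exactly 1 gene symbol stood outside the counts of genes. Of the 6829 tested, 68 were higher and 55 lower in the knockdown against mismatch shRNA, where mismatch against no treatment gave 11 and 6.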

How the results depend on the processing

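All alternatives were planned except leaving out CT2 mismatch replicate 2 with H9 untreated replicate 1, and the block with crossed replicate numbers, which were chosen after the data were seen. Of 153 results for named genes, 96 kept their direction and their side of the threshold in every alternative run, 56 lost a call in some alternative, 45 of them when 1 array was left out, and 1 changed sign: JMJD1C in mismatch against no treatment ranged from -0.12 without H9 untreated replicate 2 to 0.36 without replicate 1. The minimum of 2-fold is among these alternatives and ends every call under a log2 fold change of 1 by construction. The 56 are thus partly fixed in advance, while the 45 do not rest on that minimum. Of 24 called list results, 24 were lost with an estimated correlation, which left 0 of the 7 in the main comparison, 13 in some omission of 1 array, 5 with no filter and 0 with the replicate block. A slide block was not run, since the files give no slide, and the authors' table gave no value for H9 against CT2. Signal over background limits the folds of genes at background in a group. Where no reason is given, the cause was not tested.

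The counts below are higher and lower. Median scaling left 313 lower for knockdown against mismatch in both lines, 147 in CT2, 162 for knockdown against no treatment and 617 for H9 against CT2, and it moved the median of all genes up in these. For mismatch against no treatment, no filter gave 53 higher and all kept probes gave 47 higher, both with more tests to adjust for. Fitting only the groups compared gave 293 and 452 in H9, 36 and 14 in CT2, 22 and 39 for mismatch against no treatment and 382 and 401 for knockdown against no treatment. Fewer arrays alone do not explain this, since the H9 counts rose from 138 and 218 and the CT2 counts fell from 384 and 252. Replicates differed more in CT2 mismatch (SD 0.6293) than in H9 mismatch and knockdown (0.3866 and 0.3706), and the full fit gives all groups 1 spread. Array weights gave 323 and 498 in H9, 126 and 60 in CT2, 38 higher for mismatch against no treatment and 427 and 448 for knockdown against no treatment. The replicate block gave 225 and 136 in CT2 and 35 and 48 for mismatch against no treatment, and within a line 251 and 154, and 37 and 45. The empirical Bayes step without trend and robust settings gave 201 and 137 in CT2, 37 genes for the difference between lines, and 51 and 52 for mismatch against no treatment. A minimum of 2-fold, which removes genes by construction, gave 123 and 165 in both lines, 237 higher in CT2, 36 and 35 for mismatch against no treatment, 81 and 97 for knockdown against no treatment and 494 and 740 for H9 against CT2. The replicate numbers do not pair the arrays: replicate differences of the groups correlated across genes between -0.3738 and 0.3933, with -0.3179 for knockdown and mismatch in H9 and -0.1949 in CT2, and crossing the numbers gave 623 and 439 in CT2 and 130 and 203 in H9.

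Leaving out arrays, the pair included, moved the counts of knockdown against mismatch in both lines between 164 and 1039 higher and 199 and 909 lower, in H9 between 47 and 323 and 63 and 520, and in CT2 between 30 and 1199 and 10 and 631. The difference between lines ranged from 21 to 528 genes. Mismatch against no treatment ranged from 1 to 357 higher and 16 to 266 lower, knockdown against no treatment from 62 to 424 and 88 to 480, and H9 against CT2 from 147 to 1127 and 233 to 1213. Lists past the threshold ranged from 3 to 6. In both lines the lowest counts came without CT2 knockdown replicate 2 and the highest of single omissions without CT2 mismatch replicate 1 (1039 and 746), and the pair gave 731 and 909; in CT2 the pair gave 405 and 389, for the difference 206.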

Other observations

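The values in this part were chosen after they were seen. The probes of the microRNA genes MIR302C and MIR302D, of the cluster that marks human embryonic stem cells, which lie outside the rule for named genes, were lower in the knockdown on 4 of 4 arrays. MIR302D gave -0.95 ± 0.22 against mismatch shRNA (adjusted p = 0.0141), a call lost without H9 mismatch replicate 1 (0.0648) or H9 knockdown replicate 1 (0.0828). MIR302C gave -0.95 ± 0.26 (adjusted p = 0.0362), a call lost in 6 of 8 omissions of 1 array, at 0.181 without H9 mismatch replicate 1, 0.145 and 0.0706 without H9 knockdown replicates 1 and 2, 0.0861 without CT2 mismatch replicate 2, and 0.105 and 0.0986 without CT2 knockdown replicates 1 and 2. Against untreated cells MIR302C gave -1.004 (adjusted p = 0.0418) and MIR302D gave -0.69 (adjusted p = 0.0902). These are probes of a labelled-mRNA array, and the mature microRNAs were not measured.

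Some genes were at background in 1 group of arrays and at least 4-fold above background in the other groups of its line. Off in 1 group were CRYZ and TYW3 in H9 mismatch, CAT in H9 knockdown, CSRP1, MTLN, QNG1 and TRIM68 in CT2 mismatch, and CXCL5 in CT2 knockdown, 8 in all. On in 1 group were BEX5 and QNG1 in H9 knockdown, ZNF280D in CT2 untreated and CYP2E1 in CT2 knockdown, 4 in all. Of 20 gene values low on 1 array by the same 4-fold rule, 4 were detected on its replicate (20%), and at 8-fold 0 of 4 were.

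CT2 mismatch replicate 2 differed from replicate 1 most in the list means of naive pluripotency (-0.50), haematopoietic markers (-0.49), primitive streak and mesoderm (-0.49), fibroblast markers (-0.48) and miR-302 targets (-0.38), the 5 largest in size, and the largest positive value was that of NODAL and activin response (0.33).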
